A study of Mus musculus with 2 samples.

How the data were processed

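ATAC-seq, in which a transposase cuts and tags open chromatin, was run on flow-sorted mouse alveolar macrophages, the resident phagocytes of the airspace. Per the labels, the cells were collected 72 h after inhalation of lipopolysaccharide (LPS), a bacterial cell wall component that signals through Toll-like receptor 4. Each of the 2 libraries was made from 200000 cells with a commercial kit and 10 PCR cycles, per the labels. The labels give 1 group with replicates 1 and 2, and nothing in them says that the replicates came from separate animals, so the spread between them may be technical. No unexposed cells were analysed here, and no value below measures an effect of LPS.

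Trim Galore, Bowtie2, MACS2 version 2.1.0 and the mouse build mm10 are named in the submitters' processing notes, without their parameters. Whether reads were shifted for the transposase offset, and whether duplicate or mitochondrial reads were removed, is not given in the sources used here. Peaks were called separately for each library, since the deposited data hold 1 peak list per library. The deposited fold enrichment is a ratio of the signal at a summit to the peak caller's background. Strength was deposited by the authors as −log10 p and −log10 q at each summit, and every −log10 q was above 2. The deposited score was 10 times the −log10 q, cut to a whole number, with a largest difference of 1. These are the authors' values for each peak and were used only to describe, rank or filter peaks within a library. The read depth of the libraries is not given in the sources used here.

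An interval with several summits takes several lines in these lists, so lines with the same start and end were joined to 1 interval. The summit with the highest −log10 q was kept, with the highest fold of any summit of the interval. Intervals outside chromosomes 1 to 19, X and Y were counted and left out. Intervals of both libraries that overlapped by at least 1 bp were merged to a shared peak, with the highest fold and −log10 q of its intervals in each library. The overlap of the libraries was set against 1000 placements of the intervals of replicate 2 at random on their own chromosomes, in a one-sided permutation test. Assembly gaps were not left out of these placements, because no genome sequence was used. Shares carry 95% Wilson intervals, which cover counting error only.

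Genes came from the RefSeq annotation of GRCm38, the assembly that mm10 names, as outer gene bounds for 21887 protein-coding genes. The annotation used gives no strand, transcription start sites or exons. A planned test of promoters was therefore made on gene ends, meaning within 1 kb of either outer end of a protein-coding gene. A gene whose start lies inside its outer bounds can thus be counted as having no peak, and neighbouring genes can share the peak at an end. Peaks were assigned by their summit to a gene end, a gene body or intergenic sequence. The planned exon, intron and UTR classes, motif tests and a background matched on CpG content were not run.

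Before the data were examined, 25 gene lists with 616 symbols were fixed, of which 9 symbols found no protein-coding gene. For each list, the number of genes with a shared peak at an end was compared with all other protein-coding genes by a two-sided Fisher's exact test. Distal peaks had a summit more than 1 kb from every outer end of a protein-coding gene. Peaks at starts inside gene bounds, or at starts of other gene types, thus counted as distal. Distal peaks were counted within 50 kb of either end of a gene and divided by the length of that window, as peaks per 100 kb. A list's mean was compared with 10000 random lists of the same size, matched in 10 bins of gene-end density, in a two-sided permutation test. The smallest p these random lists can give is 0.0002. Each family of 25 tests was adjusted by Benjamini-Hochberg with a threshold of 0.05. Genes are not replicates, so these tests compare lists of genes within these 2 libraries.

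Named genes followed a rule fixed before the data were examined. It took Klf4, Mertk, Pparg and Gas6, and for each list the 2 members with the strongest peak at an end by fold rank. It also took the 2 members with the most distal peaks and up to 2 with no peak at an end. Distal shared peaks within 12.5 kb of each other were joined to clusters, and the 10 clusters with the most peaks and the 5 strongest peaks of each kind were described.

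Both tests were tested on simulated data, as 200 lists of 28 genes drawn from the 21887 genes. The gene-end test gave p below 0.05 for 5% of random lists and for 98.5% of lists drawn with 6 times the odds for genes with a peak. The distal test gave 7.5% and 65%, the latter for lists drawn with 4 times the odds for genes of high distal density. Alternatives covered the −log10 q minimum, the overlap rule, the gene-end and distal windows, the matching of random lists, the stitching distance, neighbouring genes and leaving out each replicate. At gene ends, matching on gene length used a permutation test, so ranges of adjusted exact p over the alternatives include a permutation p. Python 3.11.15 was used with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.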

Results

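Open chromatin was mapped in alveolar macrophages sorted from mouse lung 72 h after LPS inhalation, in 2 libraries of 1 group. The series concerns trained immunity of these cells and the transcription factor KLF4 with the receptor MERTK in the uptake of dying cells. The design therefore asks where chromatin was open in these cells and how far the replicates agreed. Replicate 1 held 80345 peaks on chromosomes 1 to 19, X and Y, and replicate 2 held 79439, a mean of 79892 ± 641 (SD, n = 2). The median peak width was 378 bp in replicate 1 and 359 bp in replicate 2, and the peaks covered 38.1 and 35.4 Mb. The median of the authors' fold enrichment was 7.81 in replicate 1 and 7.69 in replicate 2, while the median −log10 q was 55.4 and 39.4. More intervals of replicate 1 (29.3%) than of replicate 2 (23.6%) held several summits.

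Most peaks of each library were found in the other. Of the peaks of replicate 1, 88.7% (95% Wilson interval 88.5 to 88.9) overlapped a peak of replicate 2, and 92.1% (91.9 to 92.3) of the peaks of replicate 2 overlapped one of replicate 1. Intervals placed at random overlapped in 2.95% on average in either direction (one-sided permutation p = 0.001, the smallest that 1000 placements can give). These placements ignore that open chromatin gathers at gene ends, so this p does not measure how well the replicates agree. The overlap made 70922 shared peaks covering 37.8 Mb, and the covered bases had a Jaccard index of 79.1%. Across the 68438 shared peaks made of 1 interval from each library, fold enrichment had a Spearman rho of 0.937 and log2 fold a Pearson r of 0.94. Peaks are not independent replicates, so no p is given for these correlations. Summits of these pairs lay a median of 9 bp apart, and 96.6% lay within 100 bp.

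Peaks that were not found again were mostly weak. They numbered 9100 in replicate 1 and 6277 in replicate 2, with median folds of 3.99 and 4.10. In the weakest 10% of each library by −log10 q, 49.4% of replicate 1 peaks and 60.7% of replicate 2 peaks were found again. In the strongest 10%, all 8034 peaks of replicate 1 and all 7943 peaks of replicate 2 were found again.

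**Figure D1:**
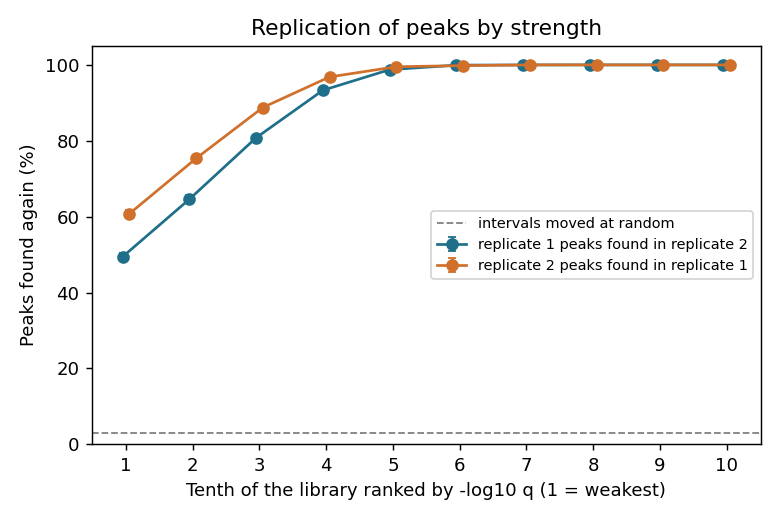
Share of peaks (%) of each library that overlapped a peak of the other, in 10 bins of −log10 q from weakest (1) to strongest (10). Bars are 95% Wilson intervals, smaller than most points, and the dashed line is the mean for intervals placed at random (2.95%). The share was 49.4% and 60.7% in the weakest bin and 100% in the strongest.

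Open chromatin was concentrated at gene ends, where the median fold was also higher than elsewhere. Of the shared peaks, 18.9% (95% Wilson interval 18.6 to 19.1) lay within 1 kb of an outer end of a protein-coding gene, sequence that makes up 2.94% of the genome, a ratio of 6.41. Gene bodies held 46.5% of shared peaks against 36.7% of the genome, and intergenic sequence held 34.7% against 60.3%. The median fold at gene ends was 14.2 in replicate 1 and 13.9 in replicate 2. It was 8.05 and 7.53 in gene bodies, and 8.46 and 8.09 in intergenic sequence. Of 21887 protein-coding genes, 12797 (58.5%) had a shared peak at an end. The mean distal density around a gene was 3.99 shared peaks per 100 kb. Chromosome X held 8.85 shared peaks per Mb, below every autosome (20.1 to 44.3). These counts were not corrected for the number of copies of a chromosome, so the low value need not reflect chromatin.

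Klf4, a zinc finger transcription factor, had its open regions of highest fold away from the gene. Klf4 lies on chromosome 4 from 55527137 to 55532475 (GRCm38), and 12 shared peaks fell within 50 kb of it, 11 of them distal. The peak over its upper end (55532216 to 55533171) had folds of 6.03 in replicate 1 and 6.80 in replicate 2. These lay at percentiles 37.9 and 43.9 of all peaks of the library. A distal intergenic peak 18.2 kb below the gene (55508545 to 55509376) reached 25.9 and 24.6. Another, 12.3 kb below the gene (55514701 to 55515364), reached 24.1 and 22.1. The peak at the gene end had a −log10 q of 204 and 165, and the distal peak 18.2 kb away had 231 and 152. The distal peak 12.3 kb away had 386 and 228. The gene end had other peaks within 5 kb, and such peaks had the lower median fold at a like −log10 q (below).

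Mertk, a receptor tyrosine kinase that binds dying cells through the bridging ligands Gas6 and Pros1, was open at its end and along its body. Mertk lies on chromosome 2 from 128698915 to 128803162, and 21 shared peaks fell in or within 50 kb of it, 14 of them inside the gene. The peak at its lower end (128698127 to 128699349) had folds of 14.4 in replicate 1 and 15.1 in replicate 2. Inside the gene, the peak at 128770721 to 128771889 had folds of 13.5 and 13.0. The window also took in peaks at the ends of the neighbouring genes Anapc1 and Tmem87b. Gas6 (chromosome 8, 13465374 to 13494535) had 3 shared peaks, and its end peak had folds of 6.82 and 10.0. With only peaks of −log10 q of at least 10 in both libraries, 1 peak was left at Gas6.

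Pparg, the nuclear receptor required for alveolar macrophage development, had many distal peaks around it. Pparg lies on chromosome 6 from 115360879 to 115490404, with 33 shared peaks in or around it, 18 of them inside the gene. It had 26 distal peaks within 50 kb of its ends. Per 100 kb of window, Pparg had 13.0 distal peaks, at percentile 96.5 of protein-coding genes. Klf4 had 10.4 (percentile 91.8) and Gas6 had 1.55 (percentile 36.2). Mertk had 16 distal peaks and lay at percentile 84.0. The peak at the lower end of Pparg (115360755 to 115362442) had folds of 11.4 and 11.1. Inside the gene, the peak at 115374985 to 115376001 had folds of 20.4 and 20.7, and the peak at 115462843 to 115463339 had 21.7 and 18.2.

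**Figure D2:**
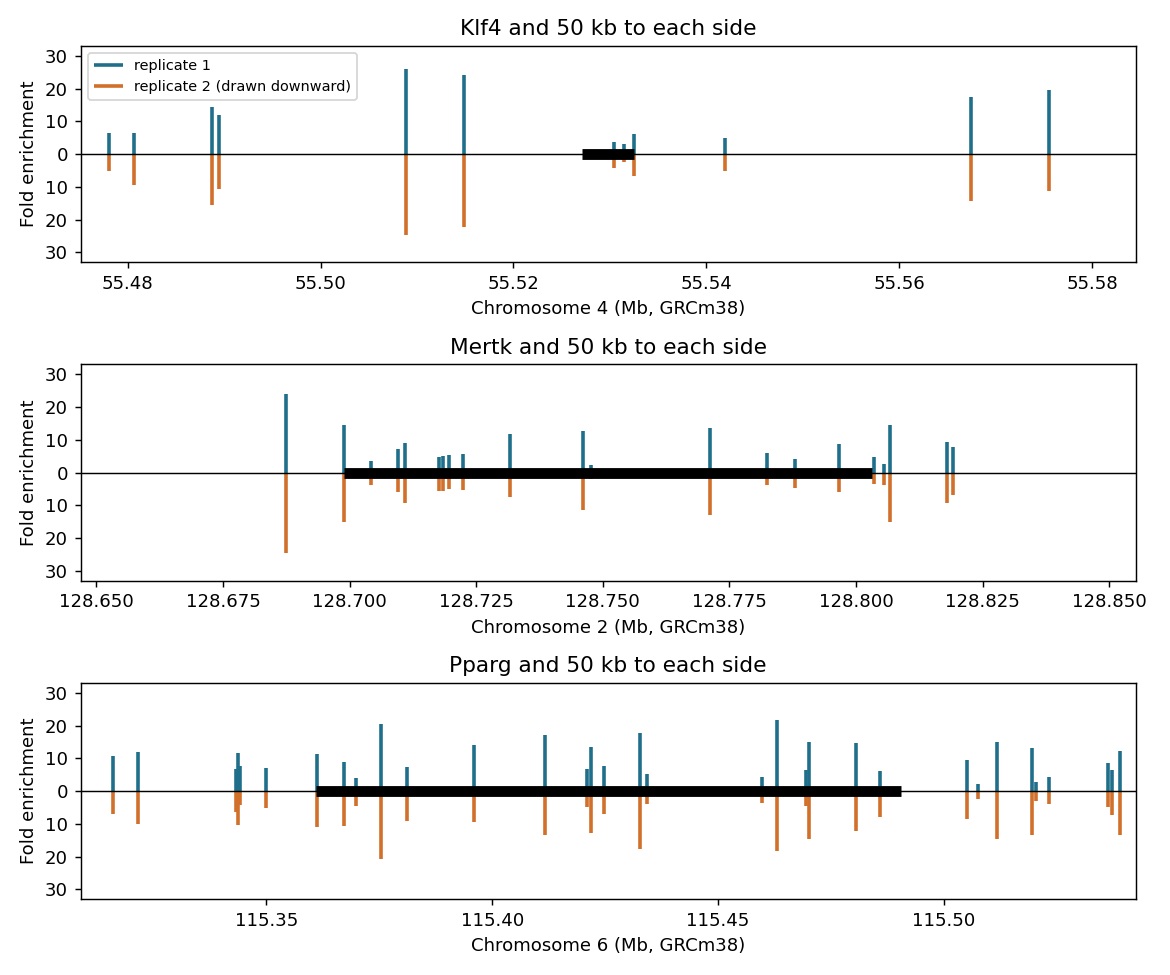
Shared peaks at Klf4, Mertk and Pparg, drawn at their summits (x axis, Mb on GRCm38) with the authors' fold enrichment in replicate 1 upward and in replicate 2 downward. Black bars are the outer bounds of each gene. The tallest Klf4 lines (25.9 and 24.6) lie below the gene, while 14 of 21 peaks at Mertk and 18 of 33 at Pparg lie inside.

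Genes of alveolar macrophage identity were open at their ends and had many distal peaks around them. A shared peak lay at an end of 26 of 28 genes (Fisher's exact test, adjusted exact p = 0.00024). Fabp5, a fatty acid binding protein, had folds of 14.8 and 15.5 at its end, and Ear1, a ribonuclease of the eosinophil-associated family, had 19.04 and 14.61. Chil3 and Il1rn had no peak at an outer end, and Il1rn, the interleukin-1 receptor antagonist, had 20 distal peaks around it. The list had 13.5 distal peaks per 100 kb against 3.62 in random lists, a ratio of 3.72 (adjusted permutation p = 0.000625), the highest of the 25 lists at this window. With a window of 100 kb the ratio was 2.69, below the 2.89 of macrophage transcription factors. Cd9, a tetraspanin, had 42 distal peaks, and the chemokine gene Ccl6 had 27. The eosinophil, basophil and mast cell list had a peak at an end of 1 of 15 genes.

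Transcription factors of macrophages were open at gene ends. All 32 had a shared peak at an end (adjusted exact p = 1.08e-06), and their distal density was 12.05 per 100 kb, a ratio of 3.32 to random lists (adjusted permutation p = 0.000625). Mitf, a regulator of lysosomal genes, had folds of 23.7 and 21.9 at its end. The end peak of Nr1h2, an oxysterol receptor, also lay at an end of Pold1 and had folds of 20.5 and 21.5. Runx1 had 35 distal peaks and Fos had 24.

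Genes of interstitial or monocyte-derived macrophages were open less uniformly, and the libraries differed at them. A shared peak lay at an end of 17 of 25 genes, which did not pass the test (adjusted exact p = 0.475). Replicate 2 alone had a peak at an end of 22 of them (adjusted exact p = 0.00611, against up to 0.749 in the other alternatives), and replicate 1 alone of 17. The difference came from C1qa, C1qb, Tmem119, Arg1 and Timd4, named after their values were seen, which had a peak at an end in replicate 2 only. Whether these were weak peaks missed in replicate 1 was not tested. With −log10 q of at least 10, 52% of the list had a shared peak at an end. The gap was not particular to this list, since interferon response genes had 25 in replicate 1 and 28 in replicate 2. The chemokine receptor Cx3cr1 had folds of 26.4 and 24.1 at its lower outer end, and Selenop, a selenium carrier, had 22.5 and 20.4 at its lower end. Which end holds the start is not given by the annotation used, so these need not be promoter values. Cd163 and Folr2 had no peak at an end. Distal density was 6.78 per 100 kb, a ratio of 1.65 (adjusted permutation p = 0.00773), a call lost with a window of 100 kb (adjusted permutation p = 0.0915, the highest of 11 alternatives from 0.0015).

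Receptors and engulfment genes of efferocytosis, the uptake of dying cells, passed the distal test and not the gene-end test. Shared peaks lay at an end of 23 of 32 genes (adjusted exact p = 0.199), and distal density was 7.75 per 100 kb, a ratio of 2.08 (adjusted permutation p = 0.000625). Mfge8, a bridging protein for dying cells, had folds of 24.1 and 24.7 at its end, and Calr, which marks cells for uptake, had 22.1 and 21.5. Lrp1 had 32 distal peaks and Itgb5 had 23. Cd36 and Adgrb1 had no peak at an end, while Cd36 had 14 distal peaks. Of the other receptors of the Mertk family, named after their values were seen, Axl had an end peak with folds of 10.4 and 10.8, and Tyro3 had a peak at an end in replicate 1 only.

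Kruppel-like factors had a shared peak at an end of 13 of 17 genes (adjusted exact p = 0.199). Their distal density was 6.17 per 100 kb, a ratio of 1.77 (adjusted permutation p = 0.0188). That call was lost when random lists were matched on a peak at a gene end (adjusted permutation p = 0.176), were not matched (adjusted permutation p = 0.0593) or were matched on gene length, an alternative added after seeing the data (adjusted permutation p = 0.0953). The 11 alternatives ran from an adjusted permutation p of 0.0121 to 0.176. Klf5 had folds of 25.7 and 24.3 at its end with 1 distal peak, and Klf7 had 18.3 and 16.7. Klf6 and Klf13 had 15 distal peaks each, and Klf15 and Klf17 had no peak at an end.

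Genes of inflammatory signalling were open at their ends. Of the genes of Toll-like receptor and NF-kappaB signalling, 35 of 36 had a shared peak at an end (adjusted exact p = 1.85e-06), with a distal ratio of 2.22 (adjusted permutation p = 0.000625). Ticam1, an adaptor of Toll-like receptors 3 and 4, had folds of 27.7 and 25.7, and Nfkb1 had 27 distal peaks. Nfkb2 was the exception, with no peak at an outer end. Of the inflammatory cytokines and chemokines, 25 of 29 had a peak at an end (adjusted exact p = 0.00429), and their distal density was 10.3 per 100 kb, a ratio of 2.48 (adjusted permutation p = 0.000625). The chemokine gene Ccl2 had folds of 20.7 and 18.8 at its end. Il1b, encoding interleukin-1 beta, had 23 distal peaks and an end peak with folds of 2.39 and 3.33. Ccl5 and Csf2 had no peak at an end. The neutrophil list also passed the distal test, with a ratio of 1.93 (adjusted permutation p = 0.00111).

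Anti-inflammatory and repair factors had a shared peak at an end of 19 of 27 genes (adjusted exact p = 0.291) and a distal ratio of 2.19 (adjusted permutation p = 0.000625). Among genes apart from their neighbours, an alternative added after seeing the data, 70.8% had one, which passed (adjusted exact p = 0.0423, over a range of 0.0423 to 0.772). Areg, an epidermal growth factor receptor ligand, had folds of 21.4 and 19.6 at its end, and Hgf, hepatocyte growth factor, had 20.4 and 20.2. Il10ra had 22 distal peaks and Socs3, an inhibitor of cytokine signalling, had 21. Interferon response genes were open at an end in 25 of 29 cases (adjusted exact p = 0.00429), while their distal ratio of 1.19 did not pass (adjusted permutation p = 0.316). Ifnar1, a chain of the type I interferon receptor, had folds of 25.05 and 25.08 at its end.

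Genes of lipid handling, lysosomes and energy metabolism were nearly all open at an outer end. The counts were 29 of 30 for lipid and surfactant handling (adjusted exact p = 2.22e-05), 28 of 29 for lysosome (adjusted exact p = 2.87e-05), 21 of 22 for glycolysis (adjusted exact p = 0.000714) and 28 of 30 for oxidative phosphorylation (adjusted exact p = 0.000183). Distal ratios were 2.09 for lipid handling and 2.08 for lysosome (both adjusted permutation p = 0.000625), and 1.70 for glycolysis (adjusted permutation p = 0.0065). The ratio for oxidative phosphorylation was 1.28 (adjusted permutation p = 0.159), and passed only with a window of 100 kb, at 1.37 (adjusted permutation p = 0.0429, over a range of 0.0429 to 0.72). Abcg1, a cholesterol exporter, had 27 distal peaks, and the lysosomal protease gene Ctsd had 30. Acat1 had folds of 26.9 and 28.5 at its end. The glycolysis call was lost when random lists were matched on a peak at a gene end (adjusted permutation p = 0.154, the highest of 11 alternatives from 0.0035).

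Cell cycle genes were open at an end in 27 of 29 cases (adjusted exact p = 0.00024), with a distal ratio of 1.42 (adjusted permutation p = 0.0482). That distal call was lost without replicate 1 (adjusted permutation p = 0.0741) and in 4 other settings, over a range of 0.0204 to 0.348. Mcm3, a replication helicase subunit, had folds of 28.8 and 29.8 with 0 distal peaks around it. Chromatin regulators had a peak at an end of 19 of 24 genes (adjusted exact p = 0.0715) and a distal ratio of 1.47 (adjusted permutation p = 0.057). The first passed without replicate 1 (adjusted exact p = 0.0339) and the second without replicate 2 (adjusted permutation p = 0.0329), but not only in those settings. Over all alternatives the adjusted exact p ran from 0.000114 to 0.424 and the adjusted permutation p from 0.0207 to 0.265. Dnmt3a had no peak at an outer end and 24 distal peaks.

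Marker genes of other lineages were open less often than other genes or did not pass the test, in lists of 14 to 24 genes. A list that did not pass is not thereby shown to equal other genes. Liver genes had a peak at an end in 3 of 18 cases (adjusted exact p = 0.00103) and neuron genes in 6 of 20 (adjusted exact p = 0.023), both below other genes, as was the eosinophil, basophil and mast cell list (adjusted exact p = 0.000183). The counts were 9 of 24 for T and NK cells (adjusted exact p = 0.0933), 5 of 14 for B cells (adjusted exact p = 0.154), 8 of 18 for endothelium (adjusted exact p = 0.291) and 6 of 18 for fibroblasts and smooth muscle (adjusted exact p = 0.0871). They were 13 of 22 for epithelium (adjusted exact p = 1), 10 of 16 for dendritic cells (adjusted exact p = 0.864) and 12 of 22 for neutrophils (adjusted exact p = 0.864). Several of these results moved with the setting. The fibroblast and smooth muscle list fell below other genes in 5 alternatives, with 11.1% of genes open within 500 bp (adjusted exact p = 0.00039, over a range of 0.00039 to 0.118). Within 500 bp, 21.4% of B cell genes (adjusted exact p = 0.0218), 27.8% of endothelial genes (adjusted exact p = 0.0416) and 29.2% of T and NK cell genes (adjusted exact p = 0.0212) were open, all below other genes, and the T and NK cell list also passed in 2 other settings. Within 2 kb, 64.3% of B cell genes were open (adjusted exact p = 1). The ranges over all alternatives were 0.0218 to 1 for B cells, 0.0416 to 1 for endothelium and 0.0212 to 0.299 for T and NK cells. Single markers were nonetheless open, as Napsa of the epithelium, with folds of 23.5 and 21.6, and Bank1 of B cells, with 29.3 and 27.9.

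Neutrophil and dendritic cell genes had more distal peaks around them than random lists. The neutrophil list had 8.55 distal peaks per 100 kb, a ratio of 1.93 (adjusted permutation p = 0.00111), and 20 distal peaks lay around Fpr1, a formyl peptide receptor. The end peak of S100a8, a calcium-binding protein of neutrophils and monocytes, had folds of 20.2 and 20.1. Granule protein genes were mixed. Mmp8 had an end peak with folds of 21.9 and 23.1, and Prtn3, Camp and Lcn2 also had a shared peak at an end. Elane, Ltf, Mpo, Mmp9 and Ngp had no shared peak at an end. The dendritic cell list had a ratio of 1.83 (adjusted permutation p = 0.0121), lost with a window of 20 kb (adjusted permutation p = 0.0713, the highest of 11 alternatives from 0.003), and Sirpa had 20 distal peaks. The remaining lineage lists did not pass the distal test in the main analysis, with ratios of 0.907 for T and NK cells, 1.16 for B cells, 1.33 for epithelium, 1.19 for endothelium and 1.12 for fibroblasts and smooth muscle. Ratios were 0.701 for the eosinophil, basophil and mast cell list, 0.57 for liver and 0.536 for neuron. The liver list fell below random lists with a window of 20 kb, at a ratio of 0.374 (adjusted permutation p = 0.00833, over a range of 0.00833 to 0.844), and in 2 other settings. The neuron list did so with random lists not matched (adjusted permutation p = 0.0158) and matched on gene length, added after seeing the data (adjusted permutation p = 0.0045), over a range of 0.0045 to 0.168.

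**Figure D3:**
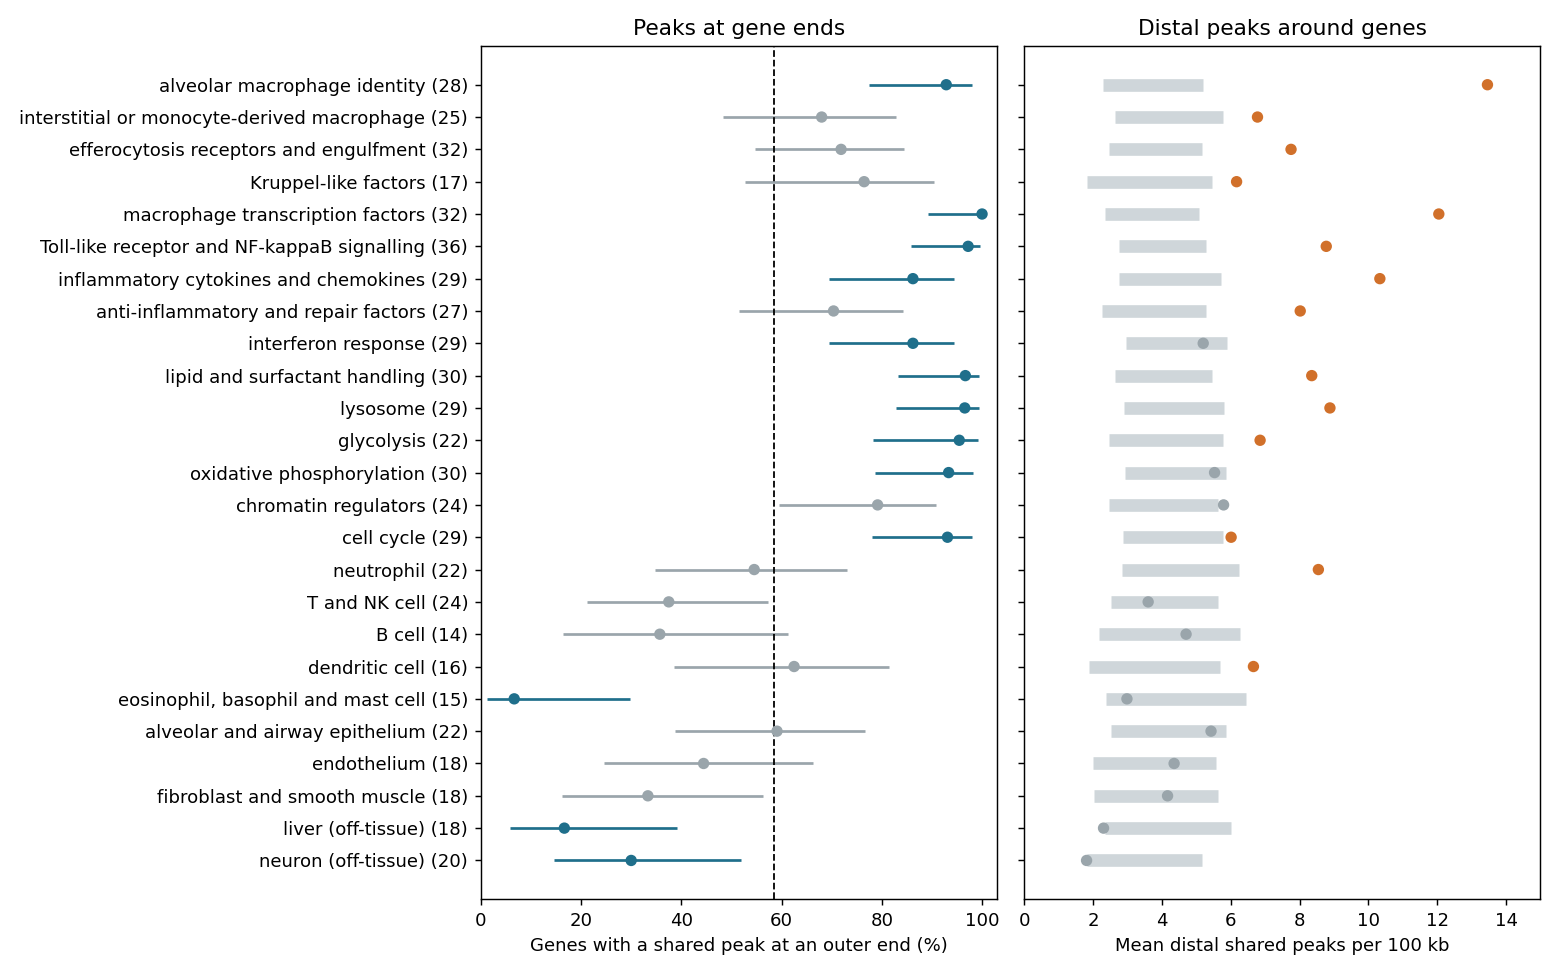
Left, genes (%) of each list with a shared peak within 1 kb of an outer end, with 95% Wilson intervals, the number of genes in parentheses and all protein-coding genes (58.5%) as a dashed line. Right, mean distal shared peaks per 100 kb of window around the genes, with the range of the middle 95% of random lists as grey bars. Coloured points passed an adjusted p of 0.05, and alveolar macrophage identity lies farthest to the right at 13.5.

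Distal peaks ranged from single peaks to clusters of up to 50. Joining neighbouring distal shared peaks gave 21048 clusters, of which 10462 held a single peak and 933 held at least 10, with 23.8% of distal peaks. The cluster with the most peaks lay in intergenic sequence on chromosome 8 from 126720541 to 126921202, with 50 peaks, 9.46 kb from Tomm20. The next held 47 peaks at Ankrd11, 44 at Cd9, 44 at Plgrkt, Cd274 and Pdcd1lg2, and 44 at Tcf7l2. Cd274 and Pdcd1lg2 encode the ligands of the inhibitory receptor PD-1. There were 42 at Ubash3b, 41 at Ube2v1, Tmem189 and Cebpb, 41 at Map3k14, Arhgap27 and Plekhm1, 41 at Prex1 and 38 at Zfp608. With a stitching distance of 5 kb, the largest count was 28 peaks and 2 of these 10 loci stayed among the 10 with the most peaks, so the ranking depends on that distance.

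Very strong peaks by −log10 q lay both at outer gene ends and more than 1 kb from them. The latter can include starts inside gene bounds, which could not be told apart here. The first at a gene end, on chromosome 5 from 34659811 to 34660861, lay at Grk4 and Nop14 with folds of 24.96 and 24.08, and was followed by peaks at B3gntl1, Ntmt1, Stip1, and C2cd3 with Ppme1. Among distal peaks, the first lay over the ribosomal RNA pseudogene Rn18s-rs5 on chromosome 17 (39843143 to 39846693). Its −log10 q was 1852 in replicate 1 and 1319 in replicate 2, while its folds were 3.04 and 3.19. The next distal peaks lay inside Zfp446 (22.9 and 23.3), 9.81 kb from Cln6 (30.1 and 29.4), inside Dgkz (20.3 and 18.7) and 14.8 kb from Kifbp (17.4 and 16.9).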

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

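All tests of explanations in this part were chosen after the results were seen. Peaks outside the assembled chromosomes were counted and used in no comparison, and their values are given here for that reason. The contig 4_GL456216_random held 6 summits in replicate 1 and 5 in replicate 2. The contig Un_JH584304 held 15 summits in replicate 1 and 11 in replicate 2, with a largest −log10 q of 2215 and 2181, above every peak on the assembled chromosomes (largest 1930 and 1459).

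Alveolar macrophage genes had more distal peaks around them than genes of interstitial or monocyte-derived macrophages, by 6.68 per 100 kb (two-sided permutation p = 0.00012, 28 and 25 genes). The difference did not shrink when the mean of each of 10 bins of gene length was removed (6.82) or of each of 10 bins of gene-end density (7.17), which argues against both as its cause. With 1 gene per 200 kb in each list, so that neighbours were not counted on the same peaks, it was 6.35 (permutation p = 0.0003). At gene ends, 26 of 28 against 17 of 25 genes had a shared peak (two-sided Fisher's exact test, p = 0.0336). With replicate 2 alone the counts were 26 of 28 and 22 of 25, closer together, so this difference depends on replicate 1. The lists were written from known markers and the design has 1 group, so no biological explanation was tested.

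Some regions with a high −log10 q had a low fold, as the end of Klf4 and the pseudogene Rn18s-rs5 did. A candidate explanation is that the caller's local background is raised by other open regions nearby. Among shared peaks of a like −log10 q, those with another within 5 kb had the lower median fold in both libraries in 10 of 10 bins. Their median was 0.499 to 0.808 of that of peaks without one, as the explanation predicts. The caller's background at these peaks and its settings are not given, so it remains a candidate. Such a neighbour was present at 65.0% of shared peaks, and whether Rn18s-rs5 had one was not examined. Reads shared between copies of ribosomal DNA were not tested and stay open for Rn18s-rs5. No biological explanation was tested.

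Replicate 1 had higher −log10 q values than replicate 2 at the same peaks, with a median ratio of 1.51. Deeper sequencing of replicate 1 is a candidate explanation. The 60 most frequent fold values fell, within 0.01 of a step, on whole multiples of 0.166 in replicate 1 and 0.228 in replicate 2, as did 24.8% and 24.0% of all lines. If the caller added 1 to signal and background and used like settings, these steps imply background pileups of 5.02 and 3.39, a ratio of 1.48. Sharper enrichment in replicate 1 is argued against by the fold ratio at the same peaks, with a median of 1.04. No biological explanation was tested.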

How the results depend on the processing

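No paired analysis was possible because the labels give 1 group. The planned motif tests, CpG-matched background and exon classes were not run, because no sequence or exon annotation was used here. Matching on gene length, restricting to genes apart from their neighbours and keeping 1 gene per 200 kb of each list were chosen after seeing the data. With 1 gene per 200 kb, no distal list call was lost or gained. The Spearman rho was 0.945 with −log10 q as the ranking value, 0.941 with reciprocal 50% overlap and 0.939 with −log10 q of at least 5. Gene ends held 14.9% of shared peaks within 500 bp, 24.8% within 2 kb, 20.5% with −log10 q of at least 10, and 17.6 to 18.3% without either replicate. For gene bodies these were 49.2%, 42.7%, 45.7% and 46.7 to 47.4%, and for intergenic sequence 35.9%, 32.5%, 33.8% and 34.9 to 35.0%. Lists below other genes at gene ends numbered 5 with −log10 q of at least 10, 7 within 500 bp and 5 with random lists matched on gene length, against 3. Lists below random lists in distal peaks numbered 1 with a window of 20 kb, 1 with 100 kb, 1 with random lists not matched and 2 with lists matched on gene length, against 0. The largest cluster held 28 peaks with a stitching distance of 5 kb, and of the main 10 clusters 2 were still among the 10 with the most peaks, or 5 with −log10 q of at least 10. The cause of these shifts was not tested. Of single list calls, 11 in the distal test and 0 in the gene-end test were lost, and 9 and 15 were gained. Direction changed for 14 list values at gene ends and 5 distal ones, none of which passed the threshold in the main or the changed setting. At gene ends these were the interstitial list (52% with −log10 q of at least 10), B cells (64.3% within 2 kb), neutrophils (52.4% among genes apart from their neighbours) and dendritic cells (56.2% with −log10 q of at least 10, 50% within 500 bp, and 62.5% within 2 kb and with matching on gene length). Epithelium changed direction at 50% with −log10 q of at least 10, 54.5% with reciprocal 50% overlap and within 500 bp, 40% among genes apart from their neighbours, and 59.1% within 2 kb and with matching on gene length, and without replicate 1 in a range of 59.1 to 68.2% without either replicate. Distal ratios did so for T and NK cells (1.02 with a window of 100 kb, 1.11 with matching on a peak at a gene end), fibroblasts and smooth muscle (0.987 with 100 kb, 0.938 with matching on gene length) and the eosinophil, basophil and mast cell list (1.39 with matching on a peak at a gene end). Read depth is not given in the sources used here, and whether depth or a difference between the libraries left peaks out of 1 of them was not tested.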

Other observations

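The gene groups and genes in this part were chosen after the data were seen. Among 153 families of protein-coding genes that share a symbol stem and have at least 15 members, 54 were open at gene ends more often than other genes and 34 less often (two-sided Fisher's exact test, Benjamini-Hochberg over the families). Olfactory and vomeronasal receptor families were almost fully closed, with a shared peak at an end of 16 of 1110 olfactory receptor genes (Olfr) and 3 of 355 vomeronasal receptor genes (Vmn). Among families open more often were 29 of 29 Mrps genes of the mitochondrial ribosome (adjusted exact p = 1.69e-06) and 34 of 35 Vps genes of vesicle sorting (adjusted exact p = 1.69e-06). The Pik genes of phosphoinositide kinases had a distal ratio of 2.53 to random lists (adjusted permutation p = 0.00588), and of 2.48 with 1 gene per 200 kb (unadjusted permutation p = 0.0002, the smallest that 10000 random lists can give). The Ccl chemokine genes, of which many lie side by side, had a ratio of 1.804 (adjusted permutation p = 0.00588), which fell to 0.932 with 1 gene per 200 kb (11 of 25 genes, unadjusted permutation p = 0.83).

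Factors that mark macrophages of other tissues differed in these cells, and 4 of the 6 examined had a shared peak at an end. Of all protein-coding genes, 58.5% had one, so this count does not set these factors apart. Gata6, of peritoneal macrophages, had an end peak with folds of 3.86 and 4.53 (percentiles 15.9 and 22.0 of all peaks of the library) and 1 distal peak. Sall1, of microglia, had no peak at an end and 0 distal peaks, and Spic, of red pulp macrophages, had a peak at an end in replicate 1 only. Sall3 had an end peak with folds of 10.4 and 10.3 and 5 distal peaks. Id1 and Id3, which act in several macrophage types, had end peaks with folds of 11.8 and 9.81 and of 13.1 and 11.4, and 18 and 14 distal peaks.

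The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had a peak at an end in both libraries, with folds of 24.0 and 23.6 at Ddx3y. Zfy1, Zfy2, Usp9y and Sry had none. Xist had 0 ends with a peak in either library and 1 peak over the gene in each.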
